A study of Mus musculus with 14 samples.

How the data were processed

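RNA abundance was measured by RNA-seq in 14 libraries of mouse lower urinary tract epithelium. Per the labels, each library held the bladder or the urethral epithelium pooled from the female embryos of a litter, with 4 litters at E14.5 and 3 at E18.5. The extraction notes instead give 3 litters for every kind of sample, and the 4 libraries of each tissue at E14.5 were taken here as 4 litters. Per the labels, poly(A) RNA was selected from 60 ng of total RNA and made into libraries with a directional kit, and pairs of reads were taken on a NovaSeq instrument. The submitters' processing notes name bcl2fastq, HISAT2 2.2.1, SAMtools 1.9 and the genome GRCm38. The deposited values were raw counts per gene symbol for 55228 genes in each of 2 tables, with no normalization by the authors that the values or labels show. The counting tool, its strand setting and the annotation release are not given in the sources used here. Counts of genes that overlap another gene on the opposite strand are therefore open to reads from that gene. Counts of close paralogs (Hba and Hbb, Ly6g2, Serpina3c, the Clca and Gsdmc families, the mast cell proteases) depend on how reads that fit several genes were counted. All mitochondrial genes had 0 counts. Gene positions are those of GRCm38.

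Library totals ran from 21.1 to 36.8 M counts. Values in CPM used effective library sizes from the trimmed mean of M values, and log2 CPM used a prior count of 2. Genes passed filterByExpr and were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold, called passing here. The groups came from the labels. The tests were bladder against urethra at each stage (the libraries of that stage alone), E18.5 against E14.5 in each tissue, and the interaction of tissue and stage (all 14 libraries, 4 groups). The litter was the replicate. Overlap expected by chance was computed from the calls of each stage as if independent.

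Replicates differed by more than counting noise. Over genes with at least 20 counts, the chi-square per gene between replicates of a group ran from 10.3 to 105.9, so no pair lay within sampling noise. Where a group had 0 counts of a gene, the fold is given as a minimum, the mean CPM of the other group over the CPM of 3 counts in that whole group. Where it had 1 to 3 counts, the ratio is given with a 95% interval from the counts and effective library sizes. These minimums and intervals cover counting error alone and leave out the variation between litters.

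Before the data were examined, 38 gene lists (600 genes) were fixed, covering urothelial and other epithelial identity, patterning, signalling, metabolism, cell state and other cell types. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01. The alternatives were camera with an estimated correlation and fry. For each list the text gives the members past the threshold in each direction and, as "alone", the number past it when p was adjusted over the members of that list. All camera p were adjusted over the lists of a comparison.

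Named genes followed a rule set at the same time. At each stage it took the 8 largest log2 fold changes in each direction with adjusted p under 0.05, at least 5 CPM in the higher group and no overlap between the groups, passing over predicted and clone symbols. For each list described it took up to 3 members with the smallest adjusted p and the strongest member that went against the majority. A panel of 15 genes was set to be reported in each comparison. A few genes, of this panel and of other parts of the rule, are not reported here. For the stage tests and the interaction it took the 6 largest changes in each direction, and Xist and the Y-linked genes served as a check of the sex label. The rule gave 137, 147, 27, 27 and 27 genes for the 5 comparisons. The genes open to the text, 49, 56, 26, 26 and 26, were picked from these with their values in view.

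Alternatives set beforehand were DESeq2 size factors within edgeR, no filter, a filter of at least 1 CPM, DESeq2 1.42.0, voom of limma, leaving out each library, a log2 fold change of at least 1, a mesenchyme score (mean log2 CPM of the mesenchyme list) as covariate, the replicate number as a block, and all 14 libraries in 1 fit. Scaling by 7 pan-epithelial genes (Epcam, Cdh1, Esrp1, Esrp2, Spint1, Spint2 and St14) and all 14 libraries with the mesenchyme covariate were added after the data were seen.

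The pipeline was tested on simulated data with the group sizes and dispersion of these data and 200 changed genes, 100 changed 2-fold and 100 changed 4-fold. Of these, edgeR recovered 42% and 73% at E14.5, 50% and 83% at E18.5, 43% and 70% for bladder stage, 43% and 71% for urethral stage, and 24% and 59% for the interaction. False calls made up 7.26, 6.34, 4.24, 2.56 and 5.68% of calls. DESeq2 made 20.1 to 29.4% false calls in the same data. With 1 of 20 simulated lists shifted, camera and fry each found that list and called no other. The genes of these lists were drawn independently of each other. This check therefore cannot show how often lists of correlated genes are called falsely. No sample was left out.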

Results

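The series set out to find which genes mark each epithelial compartment while the mouse bladder and urethra form. CD-1 female embryos were timed by vaginal plug and taken at E14.5 and E18.5. The bladder and pelvic urethra were trypsinised and parted, and the epithelium was pulled off the mesenchyme with forceps. The females of a litter made 1 pool. The data held 4 bladder and 4 urethral libraries from E14.5 and 3 of each from E18.5. Libraries detected 21966 to 24258 genes each. The 10 most counted genes took 2.80 to 4.65% of each total. The female label was checked with Xist, the noncoding RNA that silences the second X chromosome copy, which stood at 198 to 888 CPM in all 14 libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 0 to 2 counts, apart from 35 counts (0.985 CPM) in urethra E18.5 replicate 3.

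Tissue and stage separated the 14 libraries, with 34.8, 29.3 and 16.7% of the variance on the leading 3 components. Epithelial and mesenchymal genes were both present in every group. Epcam, which encodes an epithelial adhesion molecule, stood at 450 ± 27.6 CPM (SD, n = 4) in E14.5 bladder and 391 ± 79.3 CPM (n = 4) in E14.5 urethra. Col1a1, the collagen I chain made mainly by fibroblasts, stood at 790 ± 486 and 855 ± 497 CPM in the same groups. At E18.5 Epcam stood at 279 ± 55.0 CPM (n = 3) in bladder and 585 ± 34.1 CPM (n = 3) in urethra, and Col1a1 at 7683 ± 1590 and 1411 ± 108 CPM. Among the E14.5 urethral libraries, replicate 1 lay nearest the E18.5 urethra on components 1 and 3 and farthest from it on component 2.

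**Figure D1:**
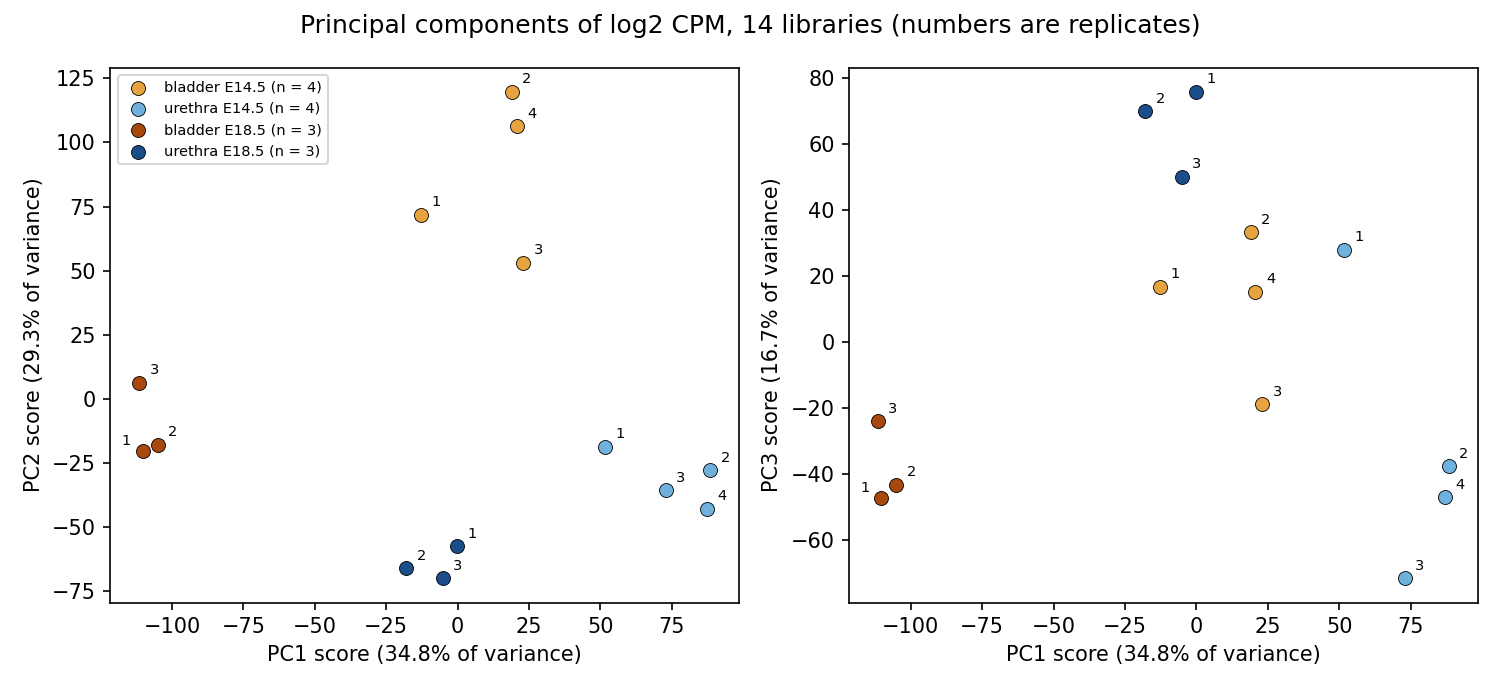
Principal component scores of log2 CPM for the 14 libraries, with components 1 and 2 on the left and 1 and 3 on the right. Each point is 1 library and its number is the replicate.

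The E14.5 comparison of bladder with urethra asked which genes set the compartments apart early. Many urothelial genes were on the bladder side. In this and the later comparisons, most list members are named where a count was 5 or fewer, which was done after their values were seen. Upk3a (chromosome 15, 85017141 to 85022547), which encodes a uroplakin of the apical urothelial plaque, was 11.1-fold higher in bladder (884 ± 392 against 77.5 ± 103 CPM, n = 4 each, log2 fold change 3.47, SE 0.89, adjusted p = 0.014). Pparg (chromosome 6, 115360951 to 115490399), a nuclear receptor needed for urothelial differentiation, was 12.1-fold higher (156 ± 35.7 against 12.5 ± 7.54 CPM, adjusted p = 0.000839). Of 10 uroplakin and superficial urothelial genes, 9 were higher in bladder (9 adjusted over the list alone), among them Upk1a (5.86-fold), Upk2 (8.11-fold) and Upk3b (10.7-fold). The camera adjusted p of this list was 0.00058, and the adjusted p = 0.492 with an estimated correlation. Of 15 urothelial transcription factors, 6 were higher in bladder (6 alone, camera adjusted p = 0.00785, adjusted p = 0.587 with an estimated correlation). Foxa1, a pioneer factor of urothelial and prostatic genes, was 2.27-fold higher (496 ± 36.1 against 212 ± 71.3 CPM, adjusted p = 0.00284). Under scaling on pan-epithelial genes, added after the data were seen, the transcription factor list split as 2 higher and 4 lower. That scaling moved the median log2 fold change of all genes to -0.985, so calls under it include this shift. Without urethra replicate 1 the log2 fold changes of Upk3a, Upk1a, Upk2 and Upk3b went from 3.47, 2.55, 3.02 and 3.42 to 5.03, 3.55, 3.65 and 4.30.

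Cholesterol synthesis, tested hindgut and most simple epithelial and tight junction genes lay on the bladder side as well. All 17 cholesterol synthesis genes were higher in bladder (17 alone, camera adjusted p = 4.96e-08, adjusted p = 0.448 with an estimated correlation), including the mevalonate pathway enzymes Mvd (68.8 ± 2.87 against 28.1 ± 5.51 CPM, 2.38-fold) and Mvk (2.01-fold). Under pan-epithelial scaling 1 of the 17 was still called. Of 14 simple epithelial genes, 9 were higher and 1, the mucin gene Muc1, lower (9 and 1 alone, camera adjusted p = 0.005, adjusted p = 0.587 with an estimated correlation). The luminal keratins Krt8 (2382 ± 218 against 713 ± 218 CPM, 3.24-fold) and Krt18 (3.64-fold) were among them. This list also holds the 7 pan-epithelial genes used for scaling, so it does not separate a simple epithelial type from the epithelial share of a library. Of 18 tight junction genes, 13 were higher and 1, the claudin gene Cldn9, lower (14 and 1 alone, camera adjusted p = 0.00262, adjusted p = 0.492 with an estimated correlation), which pan-epithelial scaling turned into 2 higher and 5 lower. The 5 tested hindgut genes Vil1, Lgals4, Cdh17, Hnf4a and Gpa33 were all higher (5 alone, camera adjusted p = 0.00647, adjusted p = 0.302 with an estimated correlation). Of these, the intestinal cadherin gene Cdh17 was 13.9-fold and the endodermal regulator Hnf4a 7.15-fold higher, with Cdh17 going from 3.79 to 4.59 log2 units without urethra replicate 3. Their levels were low. Cdh17 stood at 3.699 to 5.781 CPM in bladder and 0.164 to 0.7631 CPM in urethra, and Hnf4a at 0.9718 to 3.071 and 0.241 to 0.4099 CPM. The hindgut list held 12 genes, of which these 5 were expressed enough to be tested.

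Among the genes with the largest bladder excess at E14.5, Hsd17b2 (chromosome 8, 117701904 to 117759027), which inactivates estradiol and testosterone, was 22.9-fold higher (76.1 ± 25.4 against 3.24 ± 3.33 CPM, adjusted p = 0.0024). The plasma protein gene Ambp (29.7-fold), the vitamin C transporter gene Slc23a1 (20.3-fold), the chloride transporter gene Slc26a9 (19.7-fold), the gasdermin gene Gsdmc (19.7-fold) and Ly6g2 (24.1-fold), a member of a cell surface antigen family, followed. Ttr (chromosome 18, 20665280 to 20674321), the thyroid hormone carrier, was 18.6-fold higher (187 ± 130 against 9.80 ± 17.2 CPM, adjusted p = 0.0368). Its call was lost without bladder replicate 1 (adjusted p = 0.0793), 2 (0.0621) or 4 (0.0689), and without urethra replicate 2 (0.0834), 3 (0.081) or 4 (0.0541). Of 10 water, urea and sodium transport genes, Aqp3, Aqp11, Slc14a1, Scnn1g and Atp1b3 were higher (5, 5 alone, camera adjusted p = 0.0485, adjusted p = 0.589 with an estimated correlation). Aqp3, which encodes a water and glycerol channel, was 7.98-fold higher among them, and under pan-epithelial scaling the list split as 3 higher and 3 lower with its median turned to -0.37. The log2 fold changes of Ambp, Ly6g2, Hsd17b2, Slc23a1, Gsdmc, Ttr and Aqp3 went from 4.89, 4.59, 4.52, 4.34, 4.30, 4.22 and 3.00 to 6.63, 5.49, 5.44, 5.64, 4.91, 7.22 and 3.92 without urethra replicate 1.

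Patterning transcription factors were mostly on the urethral side at E14.5. Of 26 patterning transcription factors, 19 were higher in urethra and 2, Foxc1 and Msx2, in bladder (20 and 2 alone, camera adjusted p = 0.000128, adjusted p = 0.302 with an estimated correlation). Irx2 (chromosome 13, 72628820 to 72634198), an Iroquois homeobox gene, was 104-fold higher (0.985 ± 0.186 CPM in bladder and 101 ± 59.9 CPM in urethra, adjusted p = 0.000268), and its relative Irx5 96.6-fold. Pax9 (chromosome 12, 56691767 to 56712822), a paired box regulator of pharyngeal and oral epithelium, was 126-fold higher (0.298 ± 0.405 and 33.3 ± 16 CPM, adjusted p = 0.000591). Sox2 (chromosome 3, 34650405 to 34652461), a progenitor factor of foregut and sensory epithelium, was 7.22-fold higher (15.4 ± 3.53 and 108 ± 30.8 CPM, adjusted p = 0.000345). Hoxd13 (chromosome 2, 74668310 to 74671599), a posterior Hox gene, was 5.17-fold higher (33.3 ± 13.3 and 168 ± 33.7 CPM, adjusted p = 0.000886), and its neighbour Hoxd12 8.53-fold. Of 14 posterior Hox genes, Hoxa13, Hoxd10, Hoxd11, Hoxd12 and Hoxd13 were higher in urethra (5, 5 alone, camera adjusted p = 0.0413, adjusted p = 0.492 with an estimated correlation). Irx5 went from -6.59 to -7.67 log2 units without bladder replicate 1 and Pax9 from -6.98 to -8.44 without bladder replicate 3.

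Of 14 urogenital sinus and prostatic bud genes, 9 were higher in urethra at E14.5 and 1, the prostate protease gene Tmprss2, in bladder (10 and 1 alone, camera adjusted p = 0.00244, adjusted p = 0.302 with an estimated correlation). Foxa2 (chromosome 2, 148042877 to 148046969), a pioneer factor of endoderm, was 75.7-fold higher (0.528 ± 0.451 and 37.3 ± 13.6 CPM, adjusted p = 0.000499). Of 15 basal epithelial genes, 7 were higher in urethra (7 alone, camera adjusted p = 0.00288, adjusted p = 0.587 with an estimated correlation). The stress keratin gene Krt17 (chromosome 11, 100256217 to 100261029) was 132-fold higher (0.989 ± 0.778 and 126 ± 79.6 CPM), the suprabasal keratin gene Krt2 105-fold, and Cdh3, which encodes P-cadherin, 4.24-fold. The basal keratin gene Krt5 was 6.75-fold higher (212 ± 243 and 1390 ± 852 CPM, adjusted p = 0.024), a call lost without bladder replicate 2 (adjusted p = 0.0647) or 4 (0.0583). Trp63, the master regulator of stratified epithelium, did not pass (171 ± 46.0 and 246 ± 87.5 CPM, adjusted p = 0.132). It passed as higher in urethra with the replicate block (adjusted p = 0.00742), without urethra replicate 3 (0.0293), under pan-epithelial scaling (0.000661) and with all 14 libraries and the mesenchyme covariate (0.0319). Under pan-epithelial scaling Trp63 stood at -1.418, where the median of all genes was -0.985. Leaving out bladder replicate 1 moved Krt17 from -7.04 to -7.68, Krt2 from -6.71 to -7.41 and Krt5 from -2.75 to -3.97, and Krt2 stood at -5.98 without urethra replicate 1.

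Of 14 Wnt target genes, 13 were higher in urethra at E14.5 (13 alone, camera adjusted p = 9.78e-05, adjusted p = 0.393 with an estimated correlation). Lgr5 (chromosome 10, 115450311 to 115587780), an R-spondin receptor of epithelial stem cells, was 32.7-fold higher (1.85 ± 0.501 CPM in bladder and 58.6 ± 16.2 CPM in urethra), and the Wnt antagonist gene Apcdd1 9.29-fold. Of 17 Wnt ligand genes, 7 were higher in urethra and 2, Wnt7b and Wnt11, in bladder (7 and 2 alone, camera adjusted p = 0.00843, adjusted p = 0.393 with an estimated correlation). Wnt10b (chromosome 15, 98770712 to 98778150), a canonical ligand of epidermal appendages, had 2 counts in all 4 bladder libraries and was 364-fold higher in urethra (95% counting interval 123 to 3680, adjusted p = 0.000281). The ligand gene Wnt6 was 15.1-fold higher. Of 20 FGF genes, 8 were higher in urethra (8 alone, camera adjusted p = 0.00244, adjusted p = 0.393 with an estimated correlation), among them Etv4 (15-fold), a transcriptional readout of FGF signalling. Notch pathway genes (9 of 17, 10 alone, camera adjusted p = 0.00244) had an adjusted p = 0.393 with an estimated correlation. Wnt10b went from -8.51 to -10.67 log2 units without bladder replicate 1 and Etv4 from -3.91 to -4.56 without bladder replicate 3.

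Shh (chromosome 5, 28456815 to 28467256), the epithelial hedgehog ligand, did not pass at E14.5 (409 ± 53.2 CPM in bladder and 371 ± 90.4 CPM in urethra, adjusted p = 0.657), while under pan-epithelial scaling it passed as higher in urethra (-0.83, adjusted p = 0.00878). That change was smaller in size than the median of all genes under this scaling (-0.985). Ptch1 (chromosome 13, 63508328 to 63573598), the receptor that hedgehog signalling induces in responding cells, was 3.34-fold higher in urethra (286 ± 81.8 CPM there, log2 fold change -1.74, adjusted p = 0.0012). Of 16 hedgehog pathway genes, 9 were higher in urethra and 2, Ihh and Scube2, in bladder (10 and 2 alone, camera adjusted p = 0.00843, adjusted p = 0.456 with an estimated correlation). Of 9 mesonephric and Mullerian duct genes, 7 were higher in urethra and 1 in bladder (7 and 1 alone, camera adjusted p = 0.0258, adjusted p = 0.492 with an estimated correlation). The duct regulators Lhx1 (90.1-fold) and Pax8 (18.9-fold) and the Mullerian ligand gene Wnt7a (81.7-fold) were among them. Sox9, an endodermal bud regulator (adjusted p = 0.257), Hoxb13, a posterior Hox gene of the hindgut and prostate (0.493), Epcam (0.336) and Col1a1 (0.839) did not pass, but Sox9 passed as higher in urethra under pan-epithelial scaling (adjusted p = 0.00211) and Epcam as higher in bladder without urethra replicate 1 (0.0112). Sox9 stood at -1.285 under that scaling, against -0.985 for the median of all genes. Lhx1 (-6.49) stood at -7.51 without bladder replicate 4 and -5.72 without urethra replicate 3, Pax8 (-4.24) at -5.16 without bladder replicate 4, and Wnt7a (-6.35) at -7.65 without bladder replicate 3 and -5.65 without urethra replicate 2.

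Of 15 mesenchyme genes, 5 were higher in urethra at E14.5 (2 alone, camera adjusted p = 0.0112, adjusted p = 0.619 with an estimated correlation). The 5 were the growth factor receptor genes Pdgfra and Pdgfrb and the mesenchymal regulators Twist1, Twist2 and Prrx1. Twist1 was 7.82-fold (-2.97, and -3.89 without bladder replicate 3) and Pdgfra 3.99-fold higher, and Pdgfra lost its call without bladder replicate 4 (adjusted p = 0.0536). Of 10 smooth muscle genes, 1, the smoothelin gene Smtn, was higher in urethra (0 alone, camera adjusted p = 0.0459, adjusted p = 0.619 with an estimated correlation). By edgeR no gene passed among 12 immune genes (0 alone, camera adjusted p = 0.0344, adjusted p = 0.619 with an estimated correlation), 10 endothelial genes (0 alone, camera adjusted p = 0.411) or 10 erythroid genes (0 alone, camera adjusted p = 0.272). Of 19 cell proliferation genes, 9 were higher in bladder (9 alone, camera adjusted p = 0.0104, adjusted p = 0.619 with an estimated correlation). The mitotic cyclin gene Ccnb2 was 1.71-fold higher in bladder, but under pan-epithelial scaling the direction of the proliferation list turned (9 lower, 0 higher), as did that of Ccnb2 (-0.21).

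At E14.5 7351 of 16697 genes tested passed (44.0%), 3860 higher in bladder and 3491 higher in urethra, and the all-gene median log2 fold change was -0.035. A 2-fold minimum left 1112 on the bladder side and 1980 on the urethral side. Pan-epithelial scaling, added after the data were seen, moved the split to 540 higher in bladder and 11293 higher in urethra and the median to -0.98. With the mesenchyme score (mean log2 CPM of the mesenchyme list) as a covariate 3203 genes were called, 1675 higher in bladder and 1528 in urethra, and 42.8% of the 7351 were among them. Each library was the pool of a litter and the compartments of a stage came from the same litters, whose pairing the numbers do not give.

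The E18.5 comparison asked which genes set the compartments apart 4 days later. Stratified squamous genes were mostly on the urethral side, with 15 of 19 higher there and 2, Ivl and Sprr1a, higher in bladder (15 and 2 alone, camera adjusted p = 3.67e-05, adjusted p = 0.301 with an estimated correlation). Krt4 (chromosome 15, 101918535 to 101924735), a keratin of mucosal squamous epithelium, was 9.33-fold higher in urethra (347 ± 42.2 CPM in bladder and 3197 ± 319 CPM in urethra, n = 3 each, adjusted p = 7.02e-06). The cornified envelope gene Lor was 51.3-fold and the desmosomal plaque gene Pkp1 17.1-fold higher, while the envelope precursor gene Sprr1a was 2.79-fold higher in bladder. Krt2 and Cnfn, a cornified envelope gene, had 0 counts in bladder and were at least 571-fold and at least 241-fold higher in urethra. Of 15 basal epithelial genes, 11 were higher in urethra and 1, Pdpn, in bladder (11 and 1 alone, camera adjusted p = 0.000473, adjusted p = 0.356 with an estimated correlation), among them Krt15 (2.42-fold) and Col17a1 (6.07-fold). Of 17 dissociation stress genes, 9 were also higher in urethra and 2, Dusp1 and Hsp90aa1, in bladder (9 and 2 alone, camera adjusted p = 0.0435, adjusted p = 0.316 with an estimated correlation). Cnfn went from -11.15 to -10.10 log2 units without urethra replicate 2.

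Krt5 and Trp63 differed little at E18.5. Krt5 was 1.29-fold higher in urethra (1792 ± 202 CPM in bladder and 2283 ± 38.6 CPM in urethra, adjusted p = 0.041). Its call was lost without bladder replicate 1 (adjusted p = 0.123) or 2 (0.165) or urethra replicate 1 (0.107), 2 (0.0585) or 3 (0.0955), and with the replicate block (0.0914). The direction of Krt5 turned under pan-epithelial scaling (0.004) and with the mesenchyme covariate (0.12). Trp63 was 1.47-fold higher in urethra (171 ± 14 and 249 ± 44.5 CPM, adjusted p = 0.0189), a call lost without bladder replicate 1 (adjusted p = 0.0577) or 2 (0.0708) or urethra replicate 1 (0.0527) or 3 (0.0583).

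Patterning transcription factors were mostly on the urethral side at E18.5 too. Of 27 patterning transcription factors, 20 were higher in urethra and 4, with Tbx2, Pitx1 and Msx2 among them, in bladder (20 and 4 alone, camera adjusted p = 3.48e-06, adjusted p = 0.301 with an estimated correlation). Irx2 was 169-fold and Eya2, a coactivator of sensory and muscle development, 20.3-fold higher in urethra, and Tbx2, a T-box repressor, was 4.65-fold higher in bladder. Pax9 had 2 counts in the 3 bladder libraries and was 984-fold higher in urethra (95% counting interval 316 to 9450, adjusted p = 9.58e-06). Of 14 urogenital sinus and prostatic bud genes, 11 were higher in urethra and 1, Tmprss2, in bladder (11 and 2 alone, camera adjusted p = 9.93e-05, adjusted p = 0.316 with an estimated correlation). Sox2 (4.39 ± 0.156 and 74.2 ± 16.6 CPM, 17.1-fold), Foxa2 (27.1-fold), Sox9 (7.40-fold), Hoxd12 (12.1-fold), Hoxd13 (12.8-fold) and Hoxb13 (2.78-fold) were higher in urethra. The posterior Hox genes went both ways, with 7 of 14 higher in urethra and 3, Hoxa11, Hoxc11 and Hoxd9, in bladder (7 and 3 alone, camera adjusted p = 0.202, adjusted p = 0.538 with an estimated correlation). Pax9 (-9.94) stood at -9.29 without bladder replicate 2 and at -12.85 without bladder replicate 3.

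Of 11 neuroendocrine genes, 7 were higher in urethra at E18.5 (8 alone, camera adjusted p = 0.000206, adjusted p = 0.405 with an estimated correlation). The prohormone convertase gene Pcsk1 (0.267 ± 0.262 and 29.4 ± 2.00 CPM, 103-fold) and the serotonin synthesis gene Tph1 (44.0-fold) were among them, Pcsk1 going from -6.69 to -7.64 log2 units without bladder replicate 2. Of 14 genes of neurons and glia, 2, S100b and Ednrb, were higher in bladder (2 alone, camera adjusted p = 0.951, adjusted p = 0.986 with an estimated correlation). The amylin gene Iapp and Gad2, a GABA synthesis enzyme, had 0 counts in bladder and were at least 183-fold and at least 138-fold higher in urethra. Obp2a, an odorant-binding protein gene also at 0 counts in bladder, was at least 195-fold higher, with 2.204, 21.28 and 2.025 CPM in urethra replicates 1, 2 and 3 (-10.84, and -8.77 without urethra replicate 2). Arg1 (chromosome 10, 24915221 to 24927484), which encodes the arginase of the urea cycle, was 458-fold higher (0.961 ± 0.243 and 440 ± 21.9 CPM, adjusted p = 2.88e-07), and Clca3b, of the calcium-activated chloride channel regulator family, 702-fold. Of 19 Eph and ephrin genes, 10 were higher in urethra (10 alone, camera adjusted p = 0.000691, adjusted p = 0.316 with an estimated correlation). Shh was 1.89-fold (190 ± 31.2 and 354 ± 62.3 CPM, adjusted p = 0.00371) and Epcam 2.13-fold higher. The basal (-0.622) and Eph (-0.745) list medians were under 2-fold, so a lower epithelial share in bladder stays open.

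Bladder kept its uroplakin excess at E18.5. Upk3a was 9.01-fold (1798 ± 336 against 197 ± 62.2 CPM, log2 fold change 3.17, SE 0.26, adjusted p = 6.71e-05), Upk2 6.80-fold, Upk3b 6.01-fold and Upk1a 3.39-fold higher. Of 10 uroplakin and superficial urothelial genes, 7 were higher in bladder and 1, the uroplakin-like Upk3bl (2.74-fold), in urethra (8 and 1 alone, camera adjusted p = 0.000627, adjusted p = 0.405 with an estimated correlation). Pparg was 3.47-fold higher in bladder (113 ± 27.0 against 32.1 ± 3.10 CPM, adjusted p = 0.000169). Of 15 urothelial transcription factors, though, 10 were higher in urethra and 2, Pparg and Foxq1, in bladder (10 and 2 alone, camera adjusted p = 0.0113, adjusted p = 0.55 with an estimated correlation), and the mesenchyme covariate turned that direction (camera adjusted p = 0.834). Elf3, an epithelial ETS factor, was 3.09-fold higher in urethra, and Foxa1 did not pass (257 ± 42.4 and 324 ± 50.9 CPM, adjusted p = 0.122; 0.0465 without urethra replicate 2).

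Proliferation genes and most lipid synthesis and interferon genes were on the bladder side at E18.5. All 19 cell proliferation genes were higher in bladder (19 alone, camera adjusted p = 1.01e-08, adjusted p = 0.316 with an estimated correlation). The S phase cyclin gene Ccna2 (135 ± 10.7 against 45.7 ± 2.07 CPM, 2.92-fold) and the mitotic kinase gene Aurka (2.83-fold) were among them. Of 17 cholesterol synthesis genes, 13 were higher (15 alone, camera adjusted p = 6.28e-05, adjusted p = 0.486 with an estimated correlation), including Dhcr7 (2.15-fold), the last enzyme of the pathway. Of 14 interferon and MHC class I genes, 8 were higher and 1, Ifitm3, lower (8 and 1 alone, camera adjusted p = 0.000436, adjusted p = 0.301 with an estimated correlation), among them Bst2 (4.46-fold), an antiviral tether.

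Smooth muscle and endothelial genes and most mesenchyme and immune genes also lay on the bladder side at E18.5. Of 15 mesenchyme genes, 12 were higher (13 alone, camera adjusted p = 5.2e-06, adjusted p = 0.405 with an estimated correlation), among them the fibrillar collagen genes Col1a1 (5.37-fold, adjusted p = 3.66e-05) and Col3a1 (4.73-fold). All 10 smooth muscle genes were higher (10 alone, camera adjusted p = 9.93e-05, adjusted p = 0.467 with an estimated correlation), including the smooth muscle myosin gene Myh11 (1798 ± 750 against 160 ± 53.1 CPM, 11.1-fold), although the mesenchyme covariate turned the direction of this list (camera adjusted p = 0.0779). All 10 endothelial genes (10 alone, camera adjusted p = 3.12e-06, adjusted p = 0.316 with an estimated correlation), with the junction gene Pecam1 at 6.16-fold, were higher. So were 11 of 12 immune genes (12 alone, camera adjusted p = 3.83e-07, adjusted p = 0.316 with an estimated correlation), with the macrophage receptor gene Mrc1 at 8.60-fold. The mast cell protease genes Cma1 (44.6 ± 14.1 against 1.45 ± 1.05 CPM, 29.1-fold) and Cpa3 (33.9-fold) were among the largest differences. With them stood the serpin gene Serpina3c (87.2-fold), Ms4a4d (55.6-fold), of a membrane protein family of leukocytes, the gut hormone gene Cck (48.8-fold), the germ cell gene Asz1 (37.6-fold), the cortisone-activating enzyme gene Hsd11b1 (37.2-fold) and the carbonic anhydrase gene Car3 (27.0-fold). Of 13 skeletal muscle genes, 8 were higher in urethra and 4, Acta1, Actc1, Tnnt3 and Ckm, in bladder (8 and 4 alone, camera adjusted p = 0.0165, adjusted p = 0.538 with an estimated correlation). The embryonic myosin gene Myh3 was 35.7-fold higher in urethra and the muscle creatine kinase gene Ckm 4.80-fold higher in bladder, a direction that the mesenchyme covariate turned for Ckm (-1.34). Serpina3c went from 6.45 to 7.28 log2 units without urethra replicate 2.

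At E18.5 6635 of 17513 genes passed (37.9%), 3373 higher in bladder and 3262 in urethra, with an all-gene median of -0.026. A 2-fold minimum left 1947 and 1589. Pan-epithelial scaling moved the split to 5144 higher in bladder and 1338 higher in urethra and the median to 0.36. With the mesenchyme score as a covariate, 3 genes were called, all higher in urethra, namely Arg1, the galectin gene Lgals7 and the carbonic anhydrase gene Car12. At E18.5 91.5% of the variance of that score lay between the tissues.

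**Figure D2:**
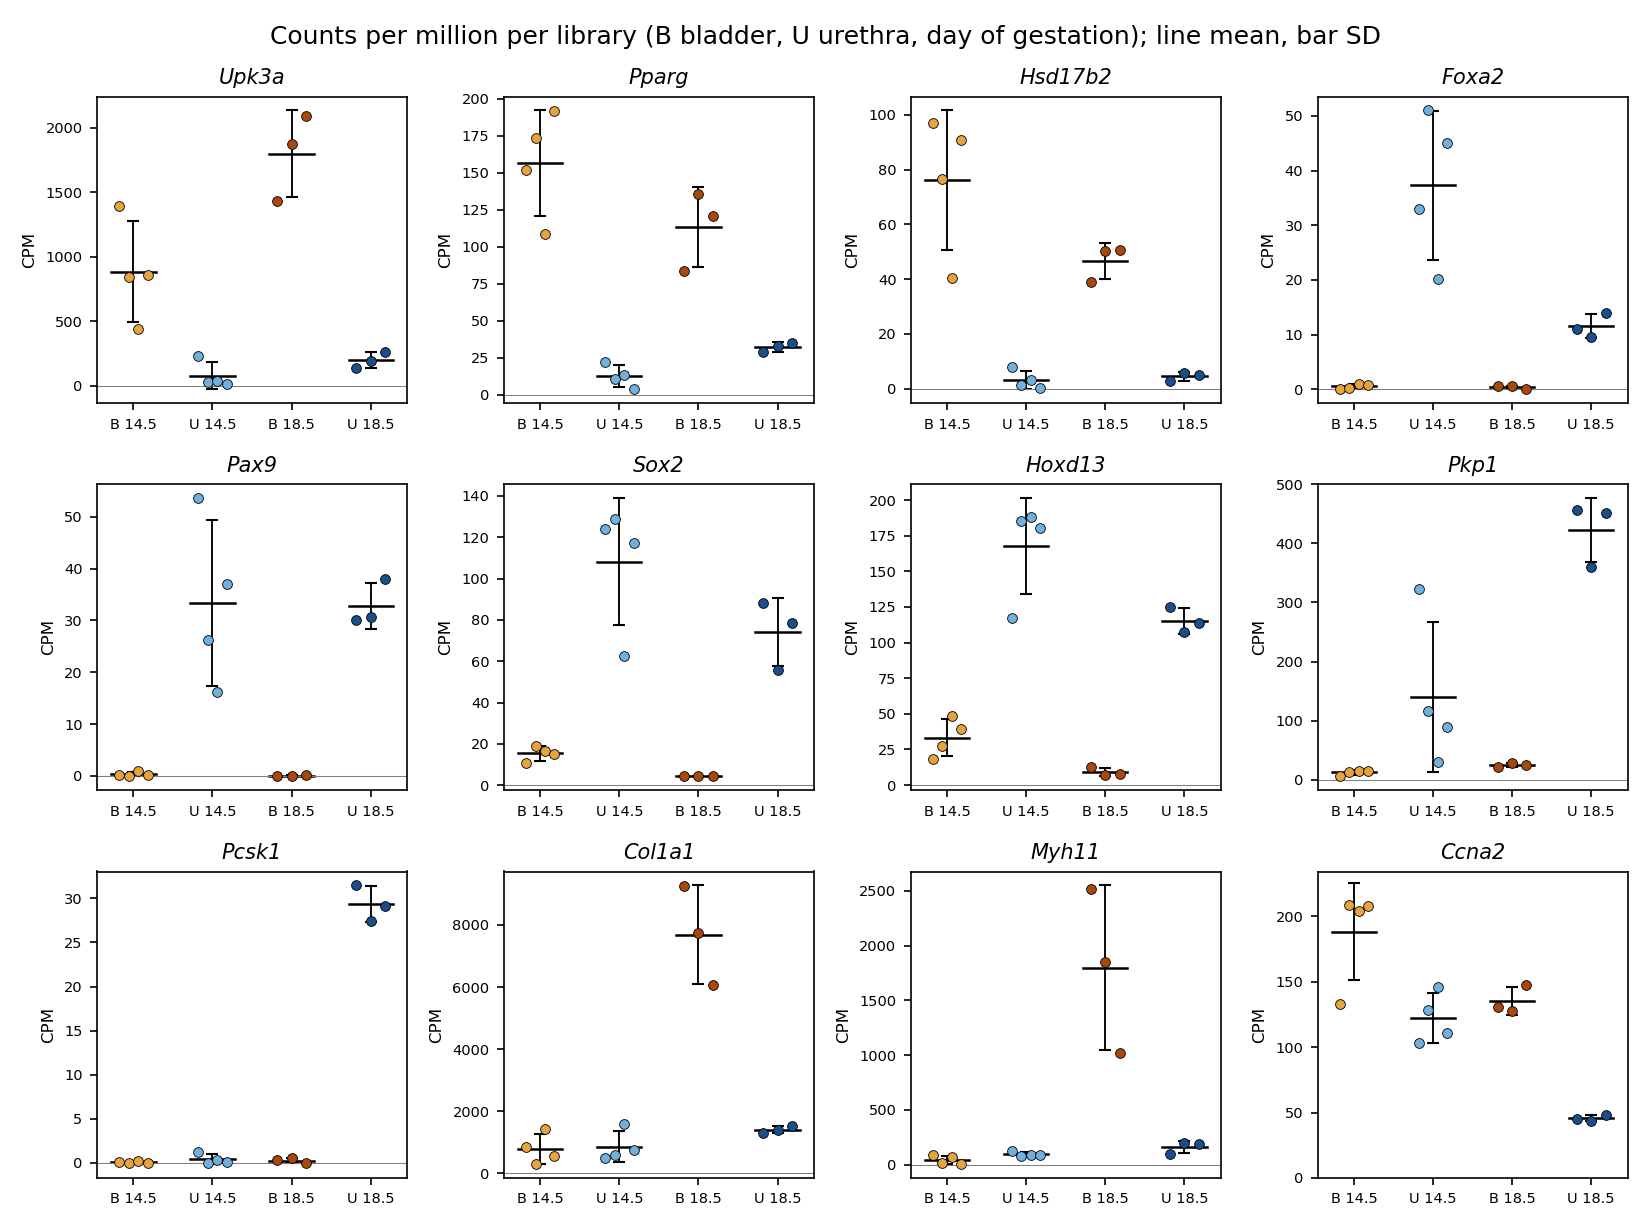
CPM of 12 genes in each of the 14 libraries, with the mean as a line and the SD as a bar. Pan-epithelial scaling, which moves all genes towards bladder at E18.5, kept the tissue direction there of the 11 genes tested under it (Hsd17b2 was not).

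The stages were then set side by side to see which compartment differences were shared. Of 16343 genes tested at both, 1304 were higher in bladder at both stages (718.5 by chance) and 1469 higher in urethra at both (627.8 by chance). The urothelial genes Upk3a, Upk2 and Pparg, the steroid enzyme gene Hsd17b2 and the mevalonate gene Mvd lay on the bladder side of this overlap. The regulators Foxa2, Pax9, Irx2 and Sox2, the keratin gene Krt17 and the stem cell receptor gene Lgr5 lay on the urethral side. Opposite calls were made for 537 genes, 201 of them higher in bladder at E14.5 and in urethra at E18.5 (705.4 by chance) and 336 the reverse (639.5 by chance). The ETS factor gene Elf3 and the chloride transporter gene Slc26a9 belonged to the 201, and the hedgehog receptor gene Ptch1 to the 336. The Pearson correlation of the log2 fold changes across genes was 0.389, and genes are not independent of each other. Under pan-epithelial scaling 1312 genes had the same direction at both stages, against 2773 with the main scaling and 3 with the mesenchyme covariate. In that E18.5 covariate fit 91.5% of the variance of the score lay between the tissues. With all 14 libraries and the covariate, added after the data were seen, 2017 genes had the same direction.

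**Figure D3:**
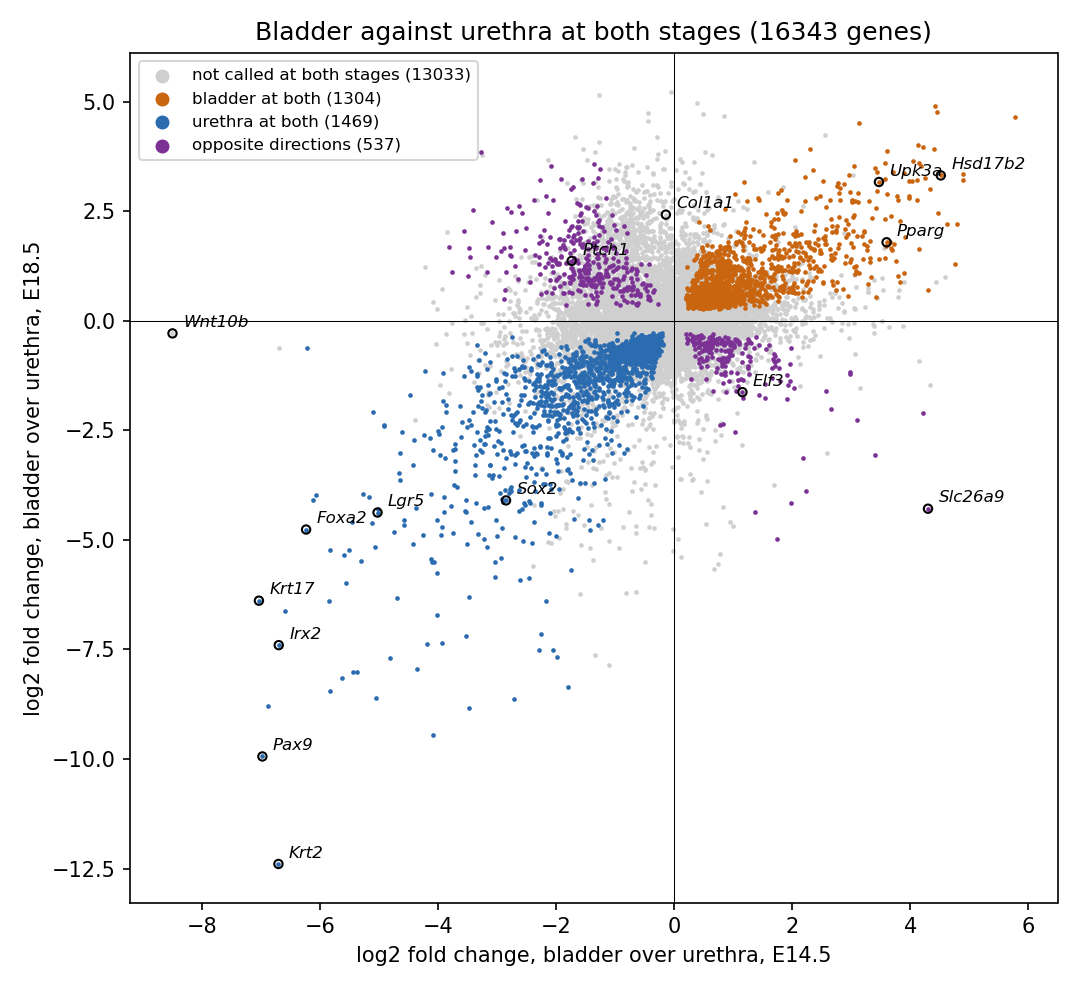
Log2 fold change of bladder over urethra at E14.5 and E18.5 for 16343 genes, coloured by calls with the main scaling. Pan-epithelial scaling lowered the genes called in the same direction at both stages to 1312.

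The bladder stage comparison asked how the bladder epithelium changed between E14.5 and E18.5. Krt5 rose 8.67-fold (212 ± 243 to 1792 ± 202 CPM, n = 4 and 3, log2 fold change 3.12, adjusted p = 0.00307), or by 4.32 without bladder E14.5 replicate 1. Of 15 basal epithelial genes, 8 rose (8 alone, camera adjusted p = 0.000575, adjusted p = 0.614 with an estimated correlation). Of the 10 uroplakin and superficial urothelial genes, 1 rose, the superficial cell keratin gene Krt20 (adjusted p = 0.00206, camera adjusted p = 0.203). Upk1a (adjusted p = 0.213), Upk2 (0.488), Upk3a (0.266), Pparg (0.402), Trp63 (0.93) and Foxa2 (0.86) did not pass, but under pan-epithelial scaling Upk1a (adjusted p = 0.00495), Upk2 (0.0267) and Upk3a (0.0323) passed as higher at E18.5. Upk1a, Upk2 and Upk3a stood at 1.36, 0.928 and 1.595 under that scaling, where the median of all genes was 0.541. Of 15 urothelial transcription factors, 8 fell (8 alone, camera adjusted p = 0.0201, adjusted p = 0.72 with an estimated correlation), and pan-epithelial scaling left 1 higher and 1 lower. The mesenchyme covariate turned the direction of that list (camera adjusted p = 0.106). Foxa1 fell by 0.92 (496 ± 36.1 to 257 ± 42.4 CPM, adjusted p = 0.00422). Shh fell by 1.08 (adjusted p = 0.000686), Hoxb13 by 2.19 (53.6 ± 16.5 to 11.5 ± 2.45 CPM, adjusted p = 0.000107), Hoxd13 by 1.83 (adjusted p = 0.00066) and Epcam by 0.66 (adjusted p = 0.00341).

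Among the genes with the largest falls in bladder, Ihh (chromosome 1, 74945315 to 74951672), the hedgehog ligand of gut and bone, fell 67.2-fold (99.3 ± 44.1 to 1.44 ± 1.26 CPM, adjusted p = 8.52e-05). The carboxylesterase gene Ces1d fell 38.5-fold, the prokineticin receptor gene Prokr2 30-fold and the embryonic claudin gene Cldn6 22.1-fold. Prokr2 (-4.91) stood at -3.62 without bladder E14.5 replicate 3. Without bladder E18.5 replicate 2 Prokr2, Ces1d (-5.27) and Cldn6 (-4.46) stood at -6.10, -6.41 and -5.34, and without E18.5 replicate 1 Ihh (-6.07) stood at -7.09. Sox9 fell by 0.92 (adjusted p = 0.0207), a call lost without bladder E14.5 replicate 1 (adjusted p = 0.0576) or E18.5 replicate 1 (0.0656) or 2 (0.0649). Of 19 cell proliferation genes, 9 fell (9 alone, camera adjusted p = 0.00487, adjusted p = 0.72 with an estimated correlation), while under pan-epithelial scaling 0 were called and the median turned to 0.09. Of 14 interferon and MHC class I genes, 13 rose (13 alone, camera adjusted p = 2.08e-08, adjusted p = 0.193 with an estimated correlation). Of 17 dissociation stress genes, 4 (Jun, Atf3, Ier3 and Dusp1) rose and 1, Dnajb1, fell (4 and 1 alone, camera adjusted p = 0.0433, adjusted p = 0.614 with an estimated correlation).

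Smooth muscle genes, immune genes and most mesenchyme genes rose in the same libraries. All 10 smooth muscle genes rose (10 alone, camera adjusted p = 7.31e-08, adjusted p = 0.613 with an estimated correlation), as did 12 of 15 mesenchyme genes (13 alone, camera adjusted p = 6.25e-07, adjusted p = 0.613 with an estimated correlation). All 12 immune genes rose (12 alone, camera adjusted p = 7.31e-08, adjusted p = 0.613 with an estimated correlation). Col1a1 rose 9.92-fold (adjusted p = 0.000192) and Ckm 1650-fold. The mast cell protease genes Tpsb2 and Mcpt4 had 0 counts at E14.5 and rose at least 1260-fold and at least 285-fold. Cma1, another mast cell protease gene, rose from 2 counts (2120-fold, 95% counting interval 749 to 22400). Serpina3c and the peptide receptor gene Npy6r, also at 0 counts at E14.5, rose at least 354-fold and at least 282-fold. Of 11 erythroid genes, 4 (the adult globin genes Hba-a1, Hbb-bs and Hbb-bt and the heme enzyme gene Alas2) rose and 2 fell (4 and 2 alone, camera adjusted p = 0.909, adjusted p = 0.984 with an estimated correlation). The 2 were the embryonic globin genes Hbb-y (732-fold) and Hba-x (217-fold, interval 59.3 to 1780, 2 counts at E18.5). Without bladder E14.5 replicate 3 Hbb-y (-9.52) and Hba-x (-7.76) stood at -7.82 and -6.54, without E18.5 replicate 2 at -8.86 and -10.62, and without E18.5 replicate 3 Hbb-y stood at -13.29. Without bladder E14.5 replicate 1 Cma1 and Ckm went from 11.05 and 10.69 to 13.24 and 11.49, and without E18.5 replicate 1 Npy6r went from 10.63 to 9.99.

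In bladder 7365 of 18286 genes passed (40.3%), 3642 higher at E18.5 and 3723 lower, with an all-gene median of -0.005. A 2-fold minimum left 2574 and 643. Pan-epithelial scaling moved the split to 6001 higher and 303 lower and the median to 0.54. With the mesenchyme covariate 650 genes were called, 249 higher and 401 lower, and 5.53% of the 7365 were among them. The stages were collected apart and library batches are not given in the sources used here, so stage cannot be parted from batch in this or the next comparison.

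The urethral stage comparison asked the same of the urethral epithelium. Most squamous and mucosal genes rose. Of 19 stratified squamous genes, 14 rose (15 alone, camera adjusted p = 8.79e-07, adjusted p = 0.386 with an estimated correlation), and Krt13 (chromosome 11, 100117327 to 100121566), a keratin of non-cornified squamous epithelium, rose 488-fold (1.62 ± 2.58 to 784 ± 308 CPM, n = 4 and 3, adjusted p = 9.07e-05). Nccrp1, a gene of squamous epithelia, rose 1560-fold. Of 13 mucosal secretory genes, 8 rose (8 alone, camera adjusted p = 0.000361, adjusted p = 0.386 with an estimated correlation). The phosphate transporter gene Slc34a2, Obp2a and the lactoferrin gene Ltf had 0 counts at E14.5 and rose at least 366-fold, at least 276-fold and at least 267-fold. Without urethra E18.5 replicate 2, which had 21.28 CPM against 2.204 and 2.025, Obp2a went from 10.83 to 8.81 log2 units, and without E14.5 replicate 1 Krt13 went from 8.93 to 11.16. Sox9 rose 1.52 log2 units (73.2 ± 27.4 to 212 ± 43.7 CPM, adjusted p = 0.00154) and Epcam 0.57 (adjusted p = 0.0102).

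Many urothelial genes rose in the urethra as well. Of 10 uroplakin and superficial urothelial genes, 7 rose (7 alone, camera adjusted p = 0.000191, adjusted p = 0.46 with an estimated correlation), also under pan-epithelial scaling. Upk1a rose 3.02-fold (211 ± 212 to 643 ± 38.1 CPM, adjusted p = 0.0299), a call lost without urethra E14.5 replicate 2 (adjusted p = 0.0883), 3 (0.0773) or 4 (0.0738) or E18.5 replicate 1 (0.0701), 2 (0.0655) or 3 (0.0678). Its log2 fold change went from 1.59 to 2.60 without E14.5 replicate 1. Upk2 (adjusted p = 0.279) and Upk3a (0.178) did not pass, but passed as higher at E18.5 without E14.5 replicate 1 (adjusted p = 0.00558 and 0.000267), and Upk3a also with voom (0.0213). Of 15 urothelial transcription factors, 8 rose (10 alone, camera adjusted p = 0.0011, adjusted p = 0.546 with an estimated correlation), and pan-epithelial scaling gave 4 higher and 4 lower. Pparg rose 2.55-fold (12.5 ± 7.54 to 32.1 ± 3.10 CPM, adjusted p = 0.0184), lost without E14.5 replicate 2 (adjusted p = 0.0523) or E18.5 replicate 2 (0.0526) or 3 (0.05).

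Among the other regulators of the urethra, Foxa1 rose 0.60 log2 units (adjusted p = 0.0424), lost without urethra E14.5 replicate 2 (adjusted p = 0.0672), 3 (0.105) or 4 (0.114) or E18.5 replicate 1 (0.143) or 3 (0.0942), and turned by pan-epithelial scaling (-0.066). Foxa2 fell by 1.71 (37.3 ± 13.6 to 11.5 ± 2.18 CPM, adjusted p = 0.0275), lost without urethra E14.5 replicate 2 (adjusted p = 0.0816) or 4 (0.0674) or E18.5 replicate 1 (0.0881), 2 (0.106) or 3 (0.0569). Shh (adjusted p = 0.764), Trp63 (0.997), Krt5 (0.447), Hoxb13 (0.188), Hoxd13 (0.165) and Col1a1 (0.255) did not pass. Under pan-epithelial scaling Shh (-0.81, adjusted p = 0.00872), Trp63 (-0.64, adjusted p = 0.0262), Hoxb13 (-1.23, adjusted p = 0.00468) and Hoxd13 (-1.38, adjusted p = 0.0119) passed as lower at E18.5. The median of all genes was -0.757 under that scaling, so Shh fell about as far as the median and Trp63 less. Col1a1 passed as higher without E14.5 replicate 3 (adjusted p = 0.048) and with the mesenchyme covariate (0.00127), whose score includes Col1a1.

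Proliferation genes fell in the urethra, and most interferon and skeletal muscle genes rose. All 19 cell proliferation genes fell (19 alone, camera adjusted p = 1.81e-14, adjusted p = 0.386 with an estimated correlation). Of 14 interferon and MHC class I genes, 13 rose (13 alone, camera adjusted p = 8.79e-07, adjusted p = 0.219 with an estimated correlation). The hindgut genes Vil1, Lgals4, Cdh17, Hnf4a and Gpa33 rose (5 of 6, 5 alone, camera adjusted p = 0.0011, adjusted p = 0.219 with an estimated correlation). The neuroendocrine genes Chga, Scg2, Calca, Tph1 and Pcsk1 rose (5 of 11, 5 alone, camera adjusted p = 0.00892, adjusted p = 0.551 with an estimated correlation). Of 17 dissociation stress genes, 12 rose and 1, Hsp90aa1, fell (13 and 1 alone, camera adjusted p = 0.000361, adjusted p = 0.386 with an estimated correlation). Of 13 skeletal muscle genes, 11 rose (13 alone, camera adjusted p = 8.79e-07, adjusted p = 0.386 with an estimated correlation), with Ckm at 440-fold (8.78, and 12.64 without E14.5 replicate 1).

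Of 10 mesonephric and Mullerian duct genes, 5 (Pax2, Lhx1, Emx2, Wnt9b and Cdh16) fell in the urethra and 2 rose (7 and 2 alone), a list that did not pass (camera adjusted p = 0.0594, adjusted p = 0.578 with an estimated correlation). Wnt9b, the ligand that induces nephrons, fell 292-fold, the potassium channel gene Kcnj16 133-fold, the kidney cadherin gene Cdh16 117-fold and the nephron factor gene Pou3f3 101-fold. Cdh16 lost its call without urethra E18.5 replicate 1 (adjusted p = 0.0526) or 2 (0.0615). E14.5 replicate 3 had 42.0 CPM of Wnt9b against 0.615, 5.17 and 6.79 in replicates 1, 2 and 4, and without it Wnt9b, Kcnj16, Cdh16 and Pou3f3 went from -8.19, -7.06, -6.87 and -6.67 to -6.46, -5.45, -6.00 and -5.29. Without E18.5 replicate 3 Kcnj16, Cdh16 and Pou3f3 stood at -10.31, -9.31 and -7.41, and Kcnj16 at -6.43 without E18.5 replicate 2. Hbb-y fell 1360-fold and Hba-x 600-fold (95% counting interval 203 to 6060, 2 counts at E18.5). Hbb-y (-10.40) and Hba-x (-9.23) stood at -9.21 and -8.20 without E14.5 replicate 3, at -11.18 and -8.63 without E18.5 replicate 2, and at -9.70 and -11.64 without E18.5 replicate 3. In all, 6031 of 18286 genes passed (33%), 3156 higher at E18.5 and 2875 lower, with an all-gene median of 0.001. A 2-fold minimum left 1647 and 920. Pan-epithelial scaling moved the split to 1055 higher and 8921 lower and the median to -0.76.

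The interaction asked which tissue differences themselves changed with stage, with positive values where the bladder side was larger at E18.5. Ptch1 went from higher in urethra at E14.5 to 288 ± 49.6 CPM in bladder and 110 ± 19.0 CPM in urethra at E18.5 (log2 interaction 3.14, adjusted p = 0.00024). Slc26a9 went the other way, from 5.78 ± 2.91 and 0.282 ± 0.151 CPM in bladder and urethra to 0.261 ± 0.184 and 5.13 ± 2.31 CPM (-8.56). The microvillus gene Vil1 (-6.69), Ihh (-6.12), the calcium-binding protein gene S100g (-6.30), the goblet cell gene Clca1 (-6.24) and the airway-type protease gene Tmprss11g (-6.94) were among the genes with the largest shifts towards urethra. The mast cell genes Cma1 (8.90), Cpa3 (7.79) and Tpsb2 (9.86), the melanocortin receptor gene Mc5r (7.63), Wnt10b (8.26) and Wnt7a (8.41) were among those with the largest towards bladder, as was Lhx1 (8.59), which lay under 5 CPM in each group and in E18.5 bladder had counts in replicate 2 alone. The call of Wnt7a was lost without bladder E18.5 replicate 2 (adjusted p = 0.302) or urethra E18.5 replicate 1 (0.0667), and that of Tpsb2 without urethra E14.5 replicate 3 (4.61, adjusted p = 1). Without bladder E14.5 replicate 1 Cma1 and Wnt10b stood at 11.08 and 10.44, without bladder E14.5 replicate 3 Cpa3 and Wnt7a at 9.34 and 9.70, without urethra E14.5 replicate 2 at 7.01 and 7.75, and without urethra E14.5 replicate 3 Cma1 at 6.98. Without urethra E14.5 replicate 1 Clca1, S100g, Tmprss11g and Vil1 stood at -7.25, -7.75, -7.96 and -7.33. Wnt7a stood at 3.97 without bladder E18.5 replicate 2, which left Clca1 at -7.04, and at 12.09 without urethra E18.5 replicate 3. With the replicate block the call of Wnt7a was lost as well (adjusted p = 0.185). Without bladder E18.5 replicate 1 Ihh and Slc26a9 stood at -7.15 and -9.25, and without urethra E18.5 replicate 2 Wnt7a and Tpsb2 at 7.82 and 10.71.

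Urothelial transcription factor and tight junction genes mostly shifted towards urethra. Of 15 urothelial transcription factors, 12 shifted that way (13 alone, camera adjusted p = 2.72e-06, adjusted p = 0.376 with an estimated correlation), 2 of them under pan-epithelial scaling. Foxa1 (-1.51, adjusted p = 0.00438) shifted, as did Pparg (-1.78, adjusted p = 0.0342), although Pparg lost its call in 9 of the 14 leave-one-out fits (adjusted p 0.0563 to 0.0836). Of 18 tight junction genes, 12 shifted towards urethra and 1, Cldn10, towards bladder (13 and 2 alone, camera adjusted p = 0.00011, adjusted p = 0.376 with an estimated correlation), and the median of that list turned to 0.028 under pan-epithelial scaling. The basal genes Krt14, Cdh3 and Pdpn shifted towards bladder (3 of 15, 3 alone, camera adjusted p = 0.157, adjusted p = 0.727 with an estimated correlation). Upk1a (adjusted p = 0.489), Upk2 (0.823), Upk3a (0.881), Trp63 (0.962), Krt5 (0.0874) and Foxa2 (0.254) did not pass. Without urethra E14.5 replicate 1 Upk1a (-1.76, adjusted p = 0.00154) and Upk3a (-1.83, adjusted p = 0.0255) passed towards urethra. Trp63 (adjusted p = 0.00451), Krt5 (0.0032) and Foxa2 (0.0169) passed towards bladder under pan-epithelial scaling. That scaling moved the median of all genes to 1.295. Trp63 (1.227) lay below this median, so its pass shows no more than the shift of all genes, and Krt5 (3.497) and Foxa2 (2.779) lay above it. Krt5 also passed with voom (adjusted p = 0.0354), with the replicate block (0.00409) and without bladder E14.5 replicate 1 (0.00381). Sox9 (-2.44, adjusted p = 0.00187) and Hoxb13 (-1.71, adjusted p = 0.00847) shifted towards urethra. So did Hoxd13 (-1.27, adjusted p = 0.0464), whose call was lost without any 1 library except bladder E14.5 replicate 1 and bladder E18.5 replicate 1 (adjusted p 0.051 to 0.0987). Shh (-0.995, adjusted p = 0.0171) lost its call without urethra E18.5 replicate 1 (adjusted p = 0.0526). Epcam shifted by -1.23 (adjusted p = 0.00222), and pan-epithelial scaling turned Shh (0.27) and Hoxd13 (0.12).

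Most mesenchyme, immune, proliferation and Wnt target genes shifted towards bladder. Of 15 mesenchyme genes, 14 shifted that way (14 alone, camera adjusted p = 3.07e-07, adjusted p = 0.376 with an estimated correlation), among them Col1a1 (2.60, adjusted p = 0.015). With them went 11 of 12 immune genes (12 alone, camera adjusted p = 2.72e-06, adjusted p = 0.376 with an estimated correlation). Of 19 cell proliferation genes, 14 shifted towards bladder (17 alone, camera adjusted p = 5.58e-07, adjusted p = 0.376 with an estimated correlation), and so did 8 of 14 Wnt target genes (8 alone, camera adjusted p = 0.00113, adjusted p = 0.376 with an estimated correlation). In all, 4183 of 18286 genes passed (22.9%), 2233 towards bladder and 1950 towards urethra, with an all-gene median of -0.014. A 2-fold minimum left 1824 and 937. Pan-epithelial scaling moved the split to 12500 and 290 and the median to 1.29, and without urethra E18.5 replicate 1 2654 genes passed. With the mesenchyme covariate 64 genes were called, 19 towards bladder and 45 towards urethra, and 1.15% of the 4183 were among them. None of the 103 camera calls of the 5 comparisons held with an estimated correlation.

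**Figure D4:**
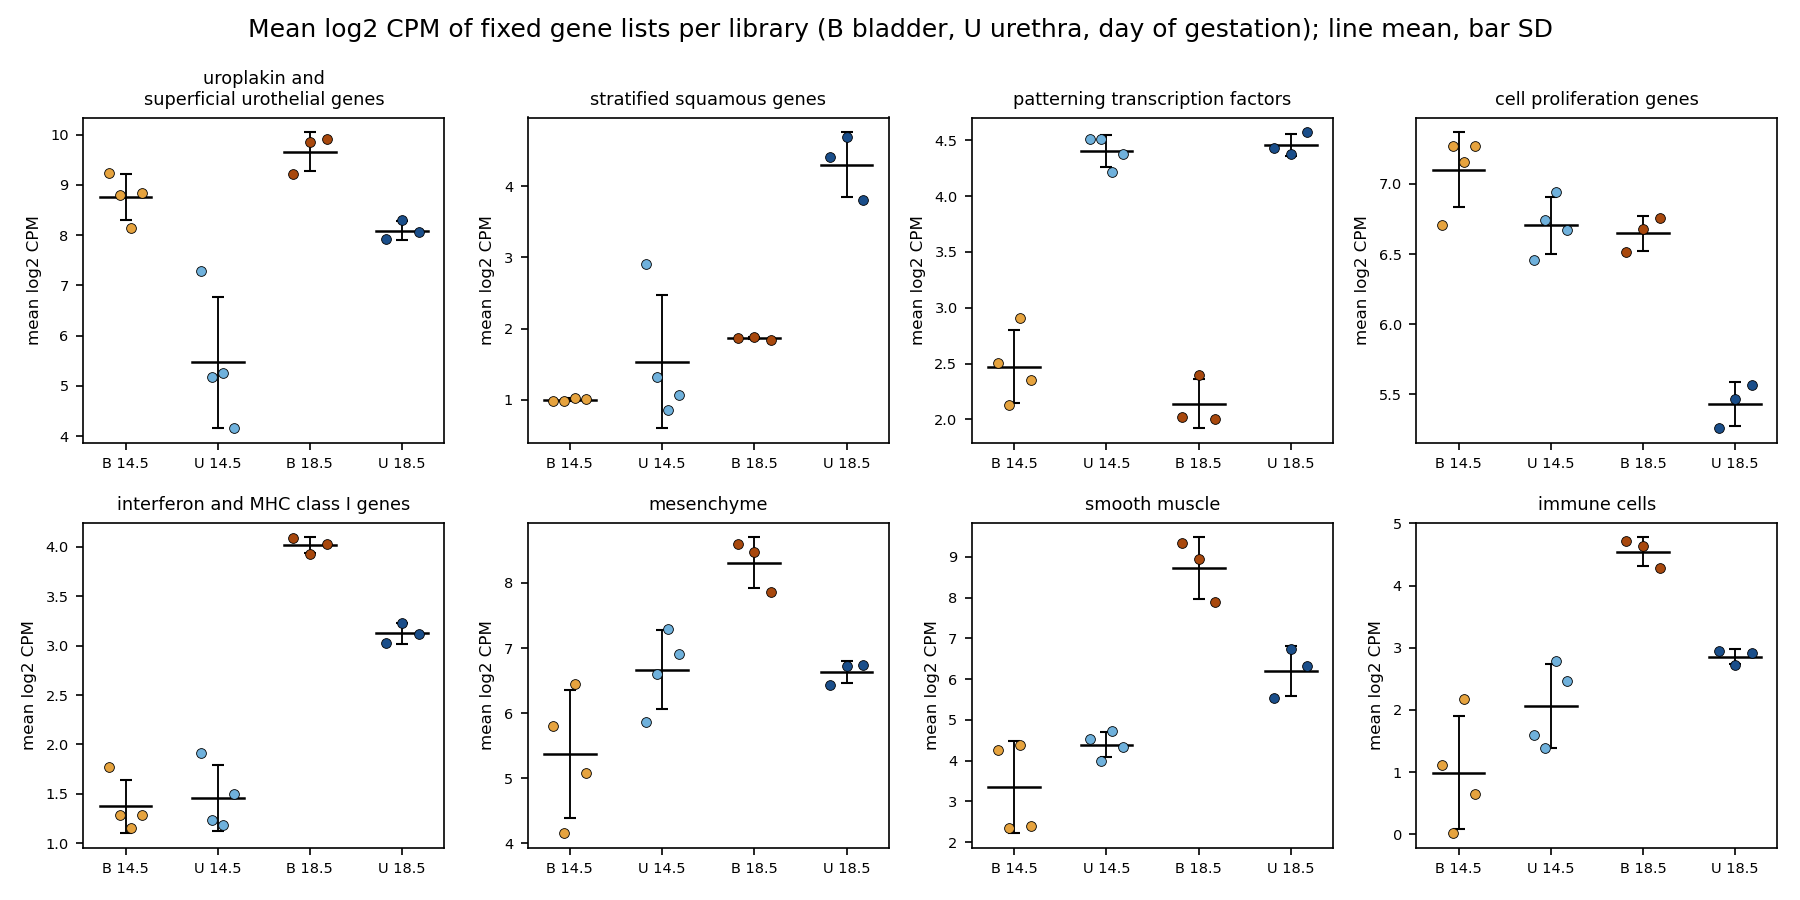
Mean log2 CPM of 8 fixed gene lists in each of the 14 libraries, with the group mean as a line and the SD as a bar. Under pan-epithelial scaling the tissue direction of the cell proliferation genes turned at E14.5 and their stage direction in bladder turned as well.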

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

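The tests of the uroplakin and proliferation genes and both tests of urethra E14.5 replicate 1 were chosen after the result was seen, and the other tests in this part were set beforehand. In 17 of 176 groups of values checked, 1 library lay far from the other 3 of its group by Dixon's ratio. About 1 in 20 groups would pass that limit by chance.

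In bladder E14.5 these were the hindgut factor gene Hnf4a (ratio 0.913, replicate 1), Hoxb13 (0.84, replicate 1), Wnt10b (1, replicate 1), the xenobiotic and antioxidant enzymes (0.915, replicate 1), the keratin gene Krt18 (0.837, replicate 3), the posterior Hox genes (0.831, replicate 3), the mevalonate gene Mvk (0.857, replicate 4) and Wnt6 (0.838, replicate 4). Of these, Mvk stood at 6.154 log2 CPM in replicate 4 against 6.22 to 6.23, and Wnt10b had counts in replicate 1 alone. In urethra E14.5, replicate 1 lay apart for Hoxd12 (0.89), Hoxd13 (0.905), Pdgfra (0.877), Ptch1 (0.867), the Wnt ligands (0.837), the Wnt target genes (0.899) and the glycolysis and hypoxia genes (0.875). Replicate 3 lay apart for Sox2 (0.868) and the urogenital sinus and prostatic bud genes (0.865).

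Tissue differences that changed with stage by the interaction test were found for 51 of the 92 genes open to the text. Over all genes tested the share was 22.9%. The 92 include genes picked for the largest interaction changes, which pass by construction, and genes picked for large tissue differences. The count of 51 is therefore no measure of how common such changes are. Towards bladder at E18.5 moved Tpsb2 (9.86), Cma1 (8.90), Cpa3 (7.79), Hsd11b1 (6.63), Myh11 (4.61), Mrc1 (3.43), Pecam1 (3.42), Twist1 (2.99), Pdgfra (2.98), Col3a1 (2.96) and Col1a1 (2.60). The same way moved Lhx1 (8.59), Wnt7a (8.41), Wnt10b (8.26), Mc5r (7.63), Ptch1 (3.14), Wnt6 (2.74), Apcdd1 (2.51) and Tbx2 (1.40). So did Asz1 (5.33), Car3 (5.21), Cck (5.01), the interferon gene Bst2 (1.98), the cadherin gene Cdh3 (1.14) and the cell cycle genes Aurka (1.14), Ccna2 (0.98) and Ccnb2 (0.96).

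Towards urethra moved Slc26a9 (-8.56), Tmprss11g (-6.94), Vil1 (-6.69), S100g (-6.30), Clca1 (-6.24), Ihh (-6.12), Clca3b (-5.30), Cdh17 (-3.23) and Hnf4a (-2.86). The same held for Arg1 (-5.32), Tph1 (-4.06), Lor (-3.90), Gsdmc (-3.58), Ly6g2 (-3.56), Elf3 (-2.75), Pparg (-1.78), Upk3bl (-1.75), Foxa1 (-1.51) and Epcam (-1.23). So did the urogenital sinus and Hox genes Sox9 (-2.44), Hoxb13 (-1.71), Hoxd13 (-1.27), Sox2 (-1.22) and Shh (-0.995).

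Of the 38 lists, 21 passed the interaction test by camera. Lists with a positive median were smooth muscle (3.30), endothelium (3.06), mesenchyme (2.96), immune cells (2.81), Wnt target genes (2.63), Wnt ligands (2.14), erythroid cells (1.9), secreted Wnt inhibitors (1.73), Notch (1.24), interferon and MHC class I (1.19), cell proliferation (0.92), hedgehog (0.91) and neurons and glia (0.82). Lists with a negative median were the mucosal secretory genes (-2.41), neuroendocrine (-2.09), hindgut (-1.91), stratified squamous (-1.64), urothelial transcription factors (-1.51), tight junction (-1.20), simple epithelial (-1.16) and uroplakin genes (-0.88). None held with an estimated correlation. With the mesenchyme covariate the direction of endothelium (adjusted p = 0.628), erythroid cells (0.00608), neurons and glia (0.00811) and the uroplakin genes (0.743) turned.

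For the E14.5 comparison, 1 of the 35 splits of the 8 libraries gave as many genes, the real split (7351, highest other 1). Litter pairing was ignored, so this count cannot decide about chance. For E18.5 there are 10 splits of the 6 libraries, too few for a share under 0.05 (real 6635, highest other 0). For the bladder stage comparison 1 of 35 splits gave as many (7365, highest other 5129, from bladder E14.5 replicate 1 grouped with the E18.5 libraries), which makes chance unlikely. For the urethral stage comparison 2 of 35 splits did (6031, highest other 6117, from urethra E14.5 replicate 1 grouped with the E18.5 libraries), so this count does not exclude chance, and it points to a structure of the samples. For the interaction 1 of 100 drawn splits gave as many (4183, highest other 3336). These splits regrouped the libraries of a stage across tissues, which breaks up the tissue difference itself. This count cannot decide either. For the overlap of the stages 1 of 100 did (2773, highest other 0), but the other splits called at most 1 gene at E14.5 and 0 at E18.5 by edgeR and so could give no overlap, and this count decides nothing about chance.

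The bladder side at E18.5 carried stromal, vascular and immune genes together with uroplakin and proliferation genes. Stromal cells carried into the E18.5 bladder libraries would leave genes that follow the mesenchyme score among the E14.5 libraries. Of the 2233 genes whose bladder side was larger by the interaction test, 2036 were tested at E14.5 and lay outside the mesenchyme list. Their median correlation was 0.701 above that of all genes (0.64 to 0.743 with each library left out). Genes that follow stroma are thus a likely part of that set. Mesenchyme list means were 5.376 and 6.669 log2 CPM in E14.5 bladder and urethra, and 8.308 and 6.634 at E18.5. The test cannot tell stroma carried into E18.5 bladder from more stroma in E14.5 urethra. Of the 3373 genes higher in bladder at E18.5, 3050 were tested at E14.5 and lay outside the mesenchyme list. Their excess was 0.188 (0.083 to 0.289) and that of the 19 proliferation genes 0.092 (-0.155 to 0.427), which decides neither. The 7 uroplakin and superficial genes higher in bladder had a median correlation below that of all genes (-0.462, from -0.701 to -0.171 with each library left out). They thus did not follow the mesenchyme score. Epithelial genes run against such a score in any mixture with stroma, so this test could hardly come out otherwise and decides little. A tissue difference in the epithelium itself stays open for them.

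Urethra E14.5 replicate 1 had more uroplakin expression than the other urethral libraries of its stage (list mean 7.28, others 4.16 to 5.26). It also had more squamous, dissociation stress (4.80, others 4.05 to 4.25) and skeletal muscle expression (1.75, others -1.26 to 0.705). Mesenchyme (5.87, others 6.61 to 7.29) and endothelium (1.57, others 3.06 to 4.13) were lower. None of these lists passed the limit of Dixon's ratio for this library. The lists that did were the Wnt ligands, the Wnt target genes and the glycolysis and hypoxia genes. Bladder epithelium carried into it would leave its squamous and basal means within the range of the other E14.5 libraries. They lay 1.587 (2.91 against 1.323) and 0.635 (7.535 against 6.9) above the highest other library. Both were beyond the SD of the other 3 urethral libraries (0.237 and 0.438). At an equal share of stroma this argues against such a mixture as the whole cause, although it stays open for the uroplakin part. An equal share was not shown, since the mesenchyme mean was lower here and the simple epithelial mean higher (7.905, other urethral libraries of E14.5 7.03 to 7.369). Of the genes higher in E18.5 urethra, at least 82.9% were higher in this library than in a held-out E14.5 library (82.9 to 90.5%). Of the lower genes at least 80.6% were lower. These shares restate its closeness to the E18.5 urethra on components 1 and 3. On component 2 it lay at -18.69, farther from the E18.5 urethra (-57.58 to -70.06) than the other E14.5 urethral libraries (-27.75 to -42.95). A more advanced state of this litter may explain the closeness on components 1 and 3, but the test of shares cannot show it. Another level of the urethra, another share of stroma and a difference in handling were not tested.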

How the results depend on the processing

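Scaling by pan-epithelial genes and all 14 libraries with the mesenchyme covariate were chosen after the data were seen, and the other alternatives were set beforehand. With DESeq2 size factors, no filter, a filter of 1 CPM, DESeq2, voom or all 14 libraries in 1 fit, no named gene turned its direction, and the calls ran from 6823 to 8432 at E14.5, 6281 to 7100 at E18.5, 6918 to 7924 for bladder stage, 5214 to 6842 for urethral stage and 3773 to 5114 for the interaction. Side of the threshold was kept by 183 of 183 named results with DESeq2 size factors, 182 of 183 with no filter, 180 of 180 at 1 CPM, 180 of 180 with DESeq2, 172 of 183 with voom and 102 of 105 with all 14 libraries.

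Leaving out 1 library gave 5593 to 8394 genes at E14.5, 4751 to 6628 at E18.5, 5952 to 7417 for bladder stage, 4062 to 7260 for urethral stage, 2654 (without urethra E18.5 replicate 1) to 5697 for the interaction and 1992 to 2802 for the overlap of the stages. Each named result was refitted without each library in turn. Of these 1456 fits, 1380 kept the side of the main fit, 67 lost the call, 9 gained it and 0 turned. Several of the lost fits belonged to the same result. For 59 of the 156 called named results a left-out library moved the fold by over 1.5 times. A 2-fold minimum left 3092, 3536, 3217, 2567 and 2761 genes and an overlap of 992, which follows from the smaller range it accepts.

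Pan-epithelial scaling called 11833 genes at E14.5, 9976 for urethral stage and 12790 for the interaction, with 6482 at E18.5, 6304 for bladder stage and an overlap of 1312. Of the genes called with the main scaling, 4025, 4710, 3945, 3927 and 2508 were also called with it. Of 183 named results, 150 kept their side with it, 12 were lost, 11 were gained and 10 turned. It turned Ccnb2 (-0.211), Shh (-0.832, adjusted p = 0.00878) and Epcam (-0.734) at E14.5, Krt5 at E18.5 (0.004), Trp63 (-0.641, adjusted p = 0.0262), Foxa1 (-0.066) and Epcam (-0.135) for urethral stage, and Shh (0.273), Hoxd13 (0.125) and Epcam (0.007) for the interaction. Epcam is among the genes it scales by, so the turns of Epcam follow from its construction. A shift of all log2 fold changes does so too, and the cause of the low pan-epithelial level behind it was not tested.

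The mesenchyme covariate called 3203 genes at E14.5, 3 at E18.5, 650 for bladder stage, 6856 for urethral stage, 64 for the interaction and 3 in the overlap. The E18.5 score lay almost wholly between the tissues (91.5% of its variance), so that fit had little tissue difference left to test, and by edgeR 880 genes higher and 1306 lower had an unadjusted p under 0.05. Of 183 named results, 91 kept their side with it, 87 were lost, 1 was gained and 4 turned. It turned Col1a1 at E14.5 (1.101), Ckm (-1.337) and Krt5 (0.117) at E18.5 and Col1a1 for the interaction (-0.242). With all 14 libraries and the covariate, 4408 genes were called at E14.5 and 3957 at E18.5, and Col1a1 at E14.5 (1.059) and Trp63 (0.026) and Krt5 (0.174) at E18.5 turned, with 79 of 105 named results kept, 22 lost and 1 gained. Col1a1 belongs to the list whose mean is the score, so its turns follow from the construction, and the cause of the other turns was not tested.

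None of the 103 camera calls held with an estimated correlation, and fry kept the side of 162 of 190 list results. The mesenchyme covariate turned 20 list results. The turn of the mesenchyme list at E14.5 (adjusted p = 0.669) follows from the score being its own mean. The others were endothelium (0.00981), immune cells (0.833) and erythroid cells (0.0491) at E14.5, and urothelial transcription factors (0.834) and smooth muscle (0.0779) at E18.5. For bladder stage they were urothelial transcription factors (0.106), Wnt ligands (0.552), Wnt targets (0.567), neuroendocrine genes (0.000712), endothelium (0.216), erythroid cells (9.83e-06) and neurons and glia (0.0015). For the interaction they were the uroplakin (0.743), posterior Hox (0.0297), retinoic acid (0.0297) and Eph genes (0.0244), endothelium (0.628), erythroid cells (0.00608) and neurons and glia (0.00811). With fry, water, urea and sodium transport turned at E18.5 (0.0426). The cause of the turns of lists other than mesenchyme was not tested.

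With the replicate block, 7680 genes were called at E14.5, 5363 at E18.5, 4322 for the interaction and 2360 in the overlap, and a random block gave 7464 for bladder stage and 6535 for urethral stage. The block changed the call of Trp63 at E14.5 (adjusted p = 0.00742), Krt5 at E18.5 (0.0914), and Wnt7a (0.185) and Krt5 (0.00409) for the interaction. The random block changed those of Hbb-y (0.396), Hba-x (0.139) and Prokr2 (0.208) for bladder stage and of Hbb-y (0.305), Hba-x (0.084), Wnt9b (0.061), Cdh16 (0.071) and Upk3a (0.0196) for urethral stage. Not every same-numbered pair of bladder and urethra libraries deviated together, and not every library correlated best with its own number (correlations 0.16, 0.134, 0.441 and -0.122 at E14.5 and 0.123, -0.136 and -0.186 at E18.5), so these values leave the pairing by litter open. In the simulation 4-fold changes were recovered for 59 to 83% of genes and 2-fold changes for 24 to 50%. Far fewer genes were changed in the simulation than passed in the data, which makes its adjusted threshold stricter. Its recovery rates therefore cannot be carried over to the real comparisons. At E14.5 7351 genes passed and a 2-fold minimum left 3092, and for bladder stage 7365 passed and 3217 were left. Many changes under 2-fold were thus called there.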

Other observations

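The mesonephric and Mullerian duct genes had list means of 3.07 ± 1.14 log2 CPM (n = 4) in E14.5 urethra, 1.48 to 4.18 over its libraries, against -0.15 ± 1.01 (n = 3) in E18.5 urethra. In bladder they had -0.17 ± 0.83 and -0.42 ± 1.80. Skeletal muscle genes had 0.159 ± 1.34 in E14.5 urethra and 4.02 ± 0.514 in E18.5 urethra, and erythroid genes 3.38 ± 1.25 and 0.952 ± 0.436.

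The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 35 counts together in urethra E18.5 replicate 3 (0.985 CPM) and 0 to 2 in each other library. The ribosomal RNA gene Gm42418 took 0.933% of the counts of bladder E18.5 replicate 2 and 0.0774 to 0.23% of the others.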
